A study of Homo sapiens with 4 samples.

How the data were processed

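Chromatin contacts were measured by Hi-C, in which crosslinked and digested chromatin is ligated so that sequences close in the nucleus are read as pairs, in VA-ES-BJ cells. Per the labels' protocols, cells were fixed with 1% formaldehyde, chromatin was cut with 3 restriction enzymes (CviQI, CviAII and BfaI), ends were filled with biotin, and libraries were sequenced as read pairs. The 4 samples are 2 of cells infected with an empty lentiviral vector and 2 of cells infected with a vector that expresses BAF47, each pair lettered A and B. Cells were selected with blasticidin at 10 µg/ml. The labels differ on the timing, giving 48 h either for virus exposure or for selection and 5 days either for selection or for growth. They do not say whether the letters stand for separate infections. The p-values from permuting the group labels therefore measure only the spread between these samples, which may be technical. P-values from counts along the chromosomes do not measure that spread.

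The authors deposited 1 list of domains (topologically associating domains, stretches of a chromosome that contact themselves more than their surroundings) per sample, with a chromosome, a start and an end and no score, count or coverage. The genome build is hg18, per the submitters' processing notes. The domain caller, the aligner, the resolution and the filters are not given in the sources used here. Replicates were not pooled, since each sample has its own list. Because the deposited lists hold no read counts, the depth of each library is unknown and no interval that needs depth was computed.

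The lists were checked before use. All starts and ends fall on a 50 kb grid, no listed domains overlap, and the 22 autosomes are listed. Domains start at position 0 in all 20 lists of the 5 acrocentric chromosomes (13, 14, 15, 21 and 22 in 4 samples), although the short arms of these chromosomes are unsequenced in hg18. The largest listed positions also lie below the known chromosome lengths. The positions therefore behave as running bin numbers from which some bins were left out, and they are not used as hg18 coordinates. Positions below are listed positions, and lengths, distances and coverage are likewise in the numbering of the lists, without the bins left out. For the same reason no gene was placed on the lists, and the gene lists fixed in advance were not analysed here.

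A step in this numbering was found in 3 blocks. Beyond a listed domain of about 12.5 Mb on chromosome 9, both BAF47 lists sit 1 bin (50 kb) higher than both empty vector lists. On chromosome 20 from about 13.75 Mb to the end, the BAF47 B list sits 1 bin lower than the other lists. An aligned version was therefore made, chosen after seeing the data. For each sample and chromosome, the offset of up to 3 bins that matched most domain starts to those of empty vector A was traced along the chromosome (Viterbi path, each change of offset costing 10 matches), and blocks of at least 10 matched starts were moved onto the numbering of empty vector A.

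A boundary was defined as a distinct domain edge, a start or an end. Edges up to 40 kb apart in 1 sample were to be joined, and boundaries up to 40 kb apart in different samples counted as shared. On the 50 kb grid this amounts to identical positions, so no edges were joined. Most neighbouring domains are 50 kb apart, so a typical boundary bin contributes 2 edges. Starts and ends were pooled, so a start in 1 sample could match an end in another. A boundary bin moved by 1 bin can thus keep 1 of its 2 edges. These rules, the comparisons, the rule for named regions and most alternatives were fixed before the data were examined. A domain was shared when both its edges were. A gained boundary was listed in both BAF47 samples and in neither empty vector sample, and a lost boundary the reverse. A split domain had the same outer edges in both empty vector samples, matched edges in both BAF47 samples, and an inner edge over 40 kb from both ends in both BAF47 samples only, and a merged domain the reverse. Because the grid is 50 kb, an end trimmed by 1 bin meets this definition. Domains with 2 or more listed domains inside were counted as well.

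Sample values were compared by an exact two-sided permutation test of the group labels, whose 6 assignments allow no p below 0.33. Agreement and counts of gained and lost boundaries were set against the 2 other ways of parting the 4 samples into pairs, with 3 splits in all. Agreement expected by chance came from 100 random circular shifts of 1 list along each chromosome (20 for whole domains). The shares of gained plus lost boundaries per chromosome were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 22 chromosomes and a threshold of 0.05, and intervals are 95% Wilson intervals that cover counting error only. The letters were not taken to pair the samples. The regions named are the 10 gained and the 10 lost boundaries farthest from any boundary of the other group, leaving out those inside an unlisted stretch of over 1 Mb in the other group, the 5 longest split and the 5 longest merged domains, the 3 chromosomes with the highest and the 3 with the lowest shares, and any chromosome past the threshold.

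Alternatives were matching distances of 0, 20, 80 and 100 kb, reciprocal overlap of 80% and 90%, no joining of edges, domain starts only, size limits of at least 100 kb and at most 2 Mb, a stricter rule for absence (100 and 200 kb), leaving out chromosome ends and unlisted stretches, leaving out each sample in turn, and pairing by letter. Added after seeing the data were the aligned numbering, boundary bins (edges joined and matched at 50 kb), leaving out chromosomes 9 and 20, and the stricter rule for splits. The scripts were tested on simulated data made from the 6530 domains of empty vector A, with 200 planted edges per direction and 3 planted steps in the numbering. The 3 steps were all recovered with 0 others called, and 86.5% of the planted edges were found after alignment. Of the edges called after alignment, 82.0% were planted ones. No single boundary was moved by 1 bin in the simulation, so calls 50 kb from an edge of the other group were not tested. Without alignment the same simulation called 638 edges, against 422 with it. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6 were used.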

Results

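Chromosome folding was compared in VA-ES-BJ cells, a line from an epithelioid sarcoma, with and without re-expression of BAF47. BAF47 is the protein of SMARCB1, a core subunit of the BAF (SWI/SNF) chromatin remodelling complex that epithelioid sarcomas commonly lack. Cells carried an empty vector (2 samples, A and B) or a vector for constitutive BAF47 expression (2 samples, A and B), and Hi-C libraries of each were reduced by the authors to 1 list of domains per sample. The lists held 6530 domains in empty vector A, 6486 in empty vector B, 6531 in BAF47 A and 6589 in BAF47 B, all on the 22 autosomes and on a 50 kb grid. Read depth is unknown, and the level of BAF47 itself was not measured by these files. The question addressed is whether restoring BAF47 changes the domain structure of the genome.

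Listed positions were in step across the 4 samples except in 3 blocks. On chromosome 9 beyond the listed domain of about 12.5 Mb, 84.2% of the 190 domain starts of BAF47 A and 79.0% of the 195 of BAF47 B matched a start of empty vector A at exactly 50 kb higher, and 6.32% and 7.18% matched at the listed position. On chromosome 20 from 13.75 Mb onwards, 83.2% of the 137 domain starts of BAF47 B matched at 50 kb lower and 4.38% as listed. The main counts and agreements are therefore given both as listed and with the numbering aligned to empty vector A, and other values are as listed unless stated. Positions are those of the lists, which leave out some bins and so do not equal hg18 coordinates. Lengths, distances and coverage likewise do not count the bins left out.

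**Figure D1:**
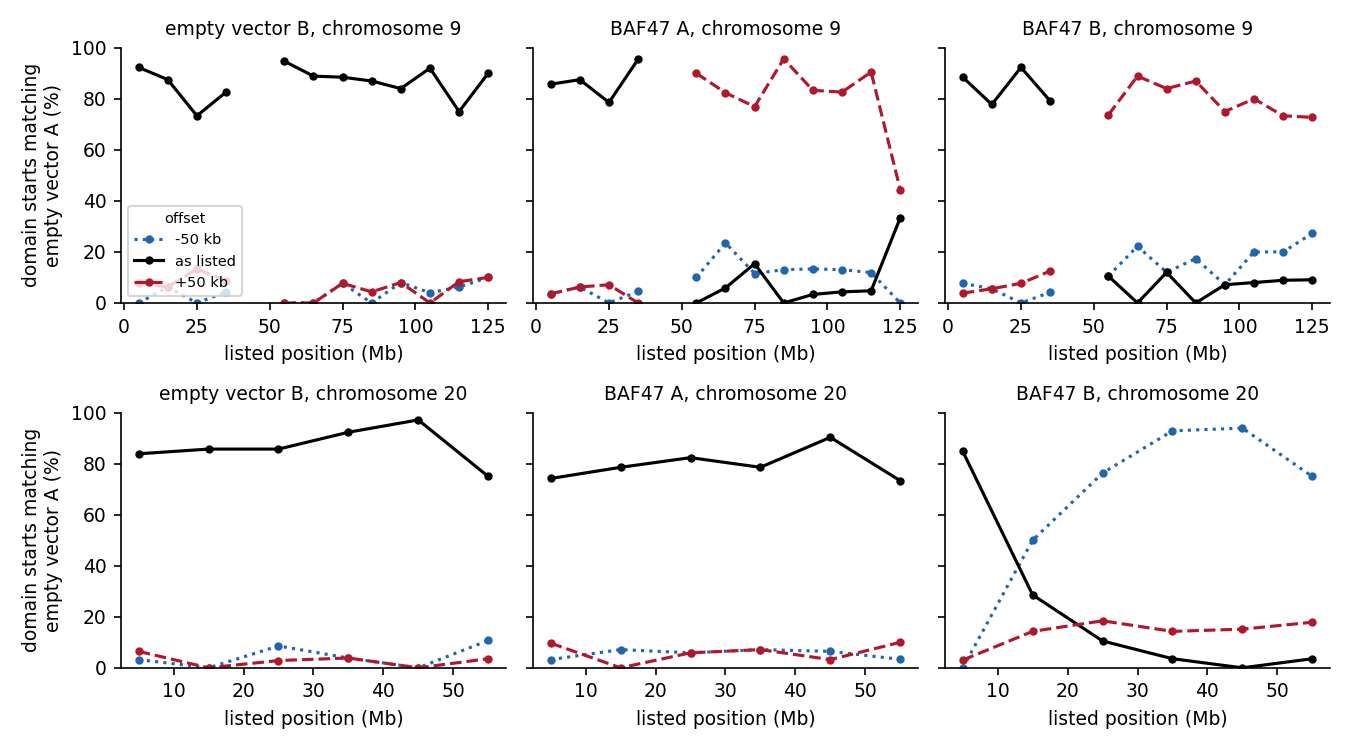
Share of domain starts (%, y axis) in 10 Mb windows along chromosome 9 (top) and chromosome 20 (bottom) that match a start of empty vector A at the listed position (black) or at 50 kb higher (red) or lower (blue), for empty vector B, BAF47 A and BAF47 B; the x axis is the listed position in Mb, and a window without domain starts has no point. Both BAF47 lists pass from the black to the red line on chromosome 9, and BAF47 B passes to the blue line on chromosome 20.

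The size of domains was alike in both conditions, and the BAF47 lists covered slightly more bins. The median domain was 200 kb long in each of the 4 samples, with quartiles of 100 and 350 kb, and the mean was 334 ± 1.15 kb with empty vector and 335 ± 1.32 kb with BAF47 (SD, n = 2). Domains covered 2174 ± 2.90 Mb with empty vector and 2198 ± 5.09 Mb with BAF47. The difference of 23.9 Mb or 1.10% exceeded the 4.1 and 7.2 Mb between replicates (exact permutation p = 0.33, the smallest this test can give). The number of domains was 6508 ± 31.1 with empty vector and 6560 ± 41 with BAF47 (SD, n = 2), a difference of 52 that was smaller than the 58 between the BAF47 replicates (exact permutation p = 0.33). This difference was 1 domain between the A samples and 103 between the B samples, and it fell to 23 without BAF47 B and 30 without empty vector B, and rose to 81 without BAF47 A. Domains over 1 Mb numbered 374.5 ± 3.54 with empty vector and 379.5 ± 2.12 with BAF47, and those over 5 Mb 16.5 ± 0.71 and 18 in each BAF47 sample. The 50 kb domains, the smallest the grid allows, numbered 1174 ± 18.4 and 1166.5 ± 34.6 (exact permutation p = 1). The smallest mean domains were on chromosomes 17 (208 ± 3.0 kb over the 4 samples, SD), 22 (215 ± 4.47 kb) and 19 (233 ± 9.62 kb), and the largest on chromosomes 13 (453 ± 11.3 kb) and 4 (426 ± 11.4 kb).

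Most domain edges were kept when BAF47 was restored. Of the 11386 domain edges listed in both empty vector samples, 86.1% were listed at the same position in both BAF47 samples, and 88.3% were with the numbering aligned. Only 5.22% of them (4.05% aligned) were in neither BAF47 sample. In all, 9806 edges (10052 aligned) were listed in all 4 samples, which is 59.1% (61.5% aligned) of the edges seen in any sample. Whole domains were kept less often than single edges. Both ends must hold, and a start cannot match an end as it can for single edges. Of 4679 domains with identical edges in both empty vector samples, 70.0% (73.6% aligned) were identical in both BAF47 samples.

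Replicates nevertheless resembled each other more than samples of different vectors did. The Jaccard index of domain edges, the share of all edges of a pair that both lists hold, was 77.7% between the empty vector samples and 77.8% between the BAF47 samples. In the 4 pairs of different vectors it ranged from 72.8% to 74.1%. The difference of the means was 4.35 percentage points, and 2.78 with the numbering aligned, where the pairs of different vectors had 75.6% to 75.8%. For whole domains the index was 55.6 ± 0.67% within groups (SD, 2 pairs) and 49.4 ± 0.83% between groups (SD, 4 pairs), a difference of 6.27 points (4.11 aligned). Randomly shifted lists shared 14% of edges and 0.69% of domains. The split by vector gave the largest difference of the 3 possible splits in both measures and both numberings. This is an exact p of 0.33 over the splits, the smallest that 3 splits allow.

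**Figure D2:**
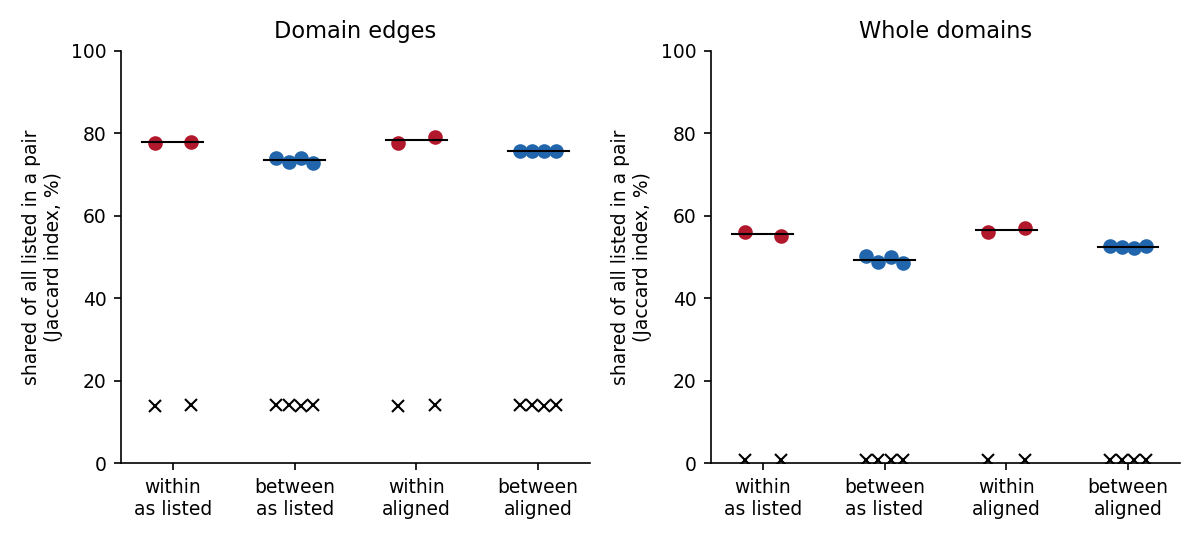
Jaccard index (%, y axis) of domain edges (left) and whole domains (right) for the 2 pairs of samples within a group (red) and the 4 pairs between groups (blue), as listed and with the numbering aligned; horizontal lines are means and crosses the mean of randomly shifted lists. Every pair within a group lies above every pair between groups.

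Boundaries specific to one condition appeared in both directions. As listed, 622 edges were gained with BAF47 and 594 were lost, but 294 of these 1216 lay on chromosome 9. With domain starts alone, 1 edge per domain, 428 were gained and 444 lost. With the numbering aligned, 488 edges were gained and 461 were lost, 7.34% of the 12923 edges that were reproducible in either group. The other 2 ways of pairing the 4 samples gave 494 edges (samples of the same letter) and 476 edges (crossed) on the aligned numbering, so the split by vector gave 1.92 times the higher of these. Of the 949 aligned edges, 603 lay exactly 50 kb from the nearest edge of the other group, the smallest step the lists can show, and 206 lay over 100 kb away, against 51 and 49 in the other splits. As listed, the counts at a matching distance of 100 kb were 104 gained and 112 lost, and edges with none of the other group within 200 kb were less even, with 37 gained and 65 lost. The other splits were not counted at 200 kb, and differing edges were grouped. Of the 949 aligned edges, a region of chromosome 8 (3.4 to 4.8 Mb) held 11 lost and 0 gained. A region of chromosome 10 (27.4 to 28.5 Mb) held 1 lost and 8 gained. With 1 of the 4 samples left out, so that a lone sample stood for its group, 1143 to 1365 were gained and 1055 to 1218 lost, and without BAF47 A 1365 and 1119. Single boundaries were not tested, since an exact test of presence in 2 samples against 2 allows no p below 0.33.

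The lost boundaries that lay farthest from any BAF47 boundary were grouped on chromosomes 5, 8, 13 and 4. On chromosome 8, edges at 3.4, 3.65, 3.7, 3.8 and 3.95 Mb were listed in both empty vector samples, 900 to 1200 kb from the nearest BAF47 edge. There, empty vector A listed 10 domains and empty vector B 8 domains between 2.35 and 6.05 Mb, where BAF47 A listed 2 and BAF47 B a single domain of 3.7 Mb. Those of the empty vector samples between 3.4 and 4.85 Mb were 50 to 150 kb long with unlisted gaps, and most differed between the samples. The edge at 3.8 Mb was a start in empty vector A and an end in empty vector B, and that at 3.95 Mb the reverse. On chromosome 5, the edges at 26.85 and 28.75 Mb of a 1.9 Mb domain of both empty vector samples lay inside a domain of 6.15 Mb in BAF47 A and of 7.75 Mb in BAF47 B, 3.05 and 1.2 Mb from the nearest edge. On chromosome 13, edges at 39.15 and 40 Mb lay inside a domain from 34.75 to 40.9 Mb that both BAF47 samples shared, and each empty vector sample listed 4 domains in that stretch. The edge at 40 Mb started a 50 kb domain in both empty vector samples. On chromosome 4, the edge at 113.35 Mb lay 900 kb from the nearest BAF47 edge, inside domains of 3.55 and 3.5 Mb. That edge ended a 50 kb domain in both empty vector samples.

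The gained boundaries farthest from any empty vector boundary lay on chromosomes 1, 2, 7, 9 and 20, leaving out 17 that fell in unlisted stretches of over 1 Mb of an empty vector list. On chromosome 2, a domain from 39.8 to 41.85 Mb in both empty vector samples was replaced by 3 domains in BAF47 A and 4 in BAF47 B, with gained edges at 40.2, 40.25, 40.45 and 40.8 Mb that lay 400 to 1000 kb from the nearest empty vector edge. On chromosome 1, edges at 210.5 and 210.55 Mb parted a 1.55 Mb domain. On chromosome 7, edges at 3.15 and 3.2 Mb parted a 1.75 Mb domain. The edge at 56.6 Mb on chromosome 20 lay 600 kb away, inside domains of 1.9 and 1.8 Mb. As listed it started a domain in BAF47 B, whose numbering sits 1 bin lower there, but in BAF47 A a domain started at 56.65 Mb. The edge at 90.35 Mb on chromosome 9 lay 450 kb away (500 kb aligned), inside a domain of 1.25 Mb. All 20 of these named edges were also gained or lost with the numbering aligned. The edges on chromosome 8 at 3.65, 3.7 and 3.95 Mb were no longer called when adjoining edges were joined into boundary bins, and those on chromosome 5 when chromosome ends and unlisted stretches were left out. With domain starts alone, 7 of the 20 were called, since the rest are domain ends in 1 or both samples.

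**Figure D3:**
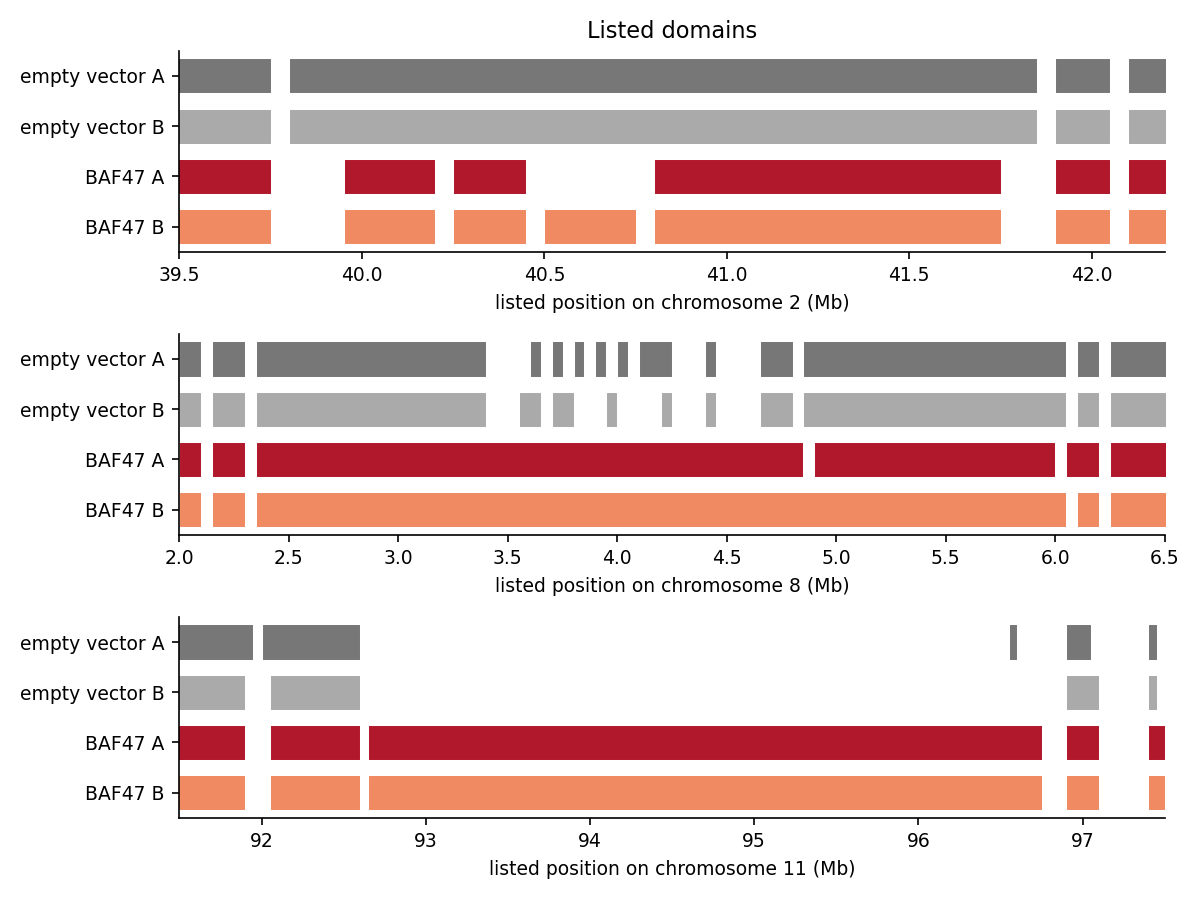
Listed domains (bars) of the 4 samples along parts of chromosomes 2 (top), 8 (middle) and 11 (bottom), with the listed position in Mb on the x axis; white is not in any listed domain. The 2.05 Mb domain of both empty vector samples on chromosome 2 is broken up in both BAF47 samples, while on chromosome 8 the short domains of the empty vector samples between 3.4 and 4.85 Mb lie inside a longer domain in each BAF47 sample, and on chromosome 11 both BAF47 samples list a domain of 4.1 Mb where the empty vector samples list a 50 kb domain or none.

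Domains with the same outer edges in both conditions were parted in either direction. As listed, 103 domains of both empty vector samples had an inner edge in both BAF47 samples, and 92 domains of both BAF47 samples had an inner edge in both empty vector samples. The other splits of the samples gave 117 and 94 such domains for both directions together, against 195. With the numbering aligned the counts were 110 and 99, and the other splits gave 124 and 100. Their median length was 300 kb in both directions as listed, and 300 and 250 kb aligned. As listed, only 48 and 32 of them held 2 or more listed domains inside the outer edges in both samples of the other group. The rest include domains trimmed at an end. A matching distance of 100 kb left 44 split and 38 merged domains. With any 1 sample left out there were 241 to 278 split and 223 to 263 merged domains. The longest split domains were a 2.4 Mb domain on chromosome 6 (21.7 to 24.1 Mb), a 2.1 Mb domain on chromosome 7 (110.15 to 112.25 Mb), a 1.75 Mb domain on chromosome 7 (2.75 to 4.5 Mb), a 1.55 Mb domain on chromosome 1 (209.6 to 211.15 Mb) and a 1.4 Mb domain on chromosome 3 (173.6 to 175.0 Mb). The first 4 held 2 domains in each BAF47 sample, and the last was trimmed by 50 kb. The longest merged domains were one of 2.85 Mb on chromosome 3 (170.75 to 173.6 Mb) and one of 1.65 Mb on chromosome 5 (93.55 to 95.2 Mb), both trimmed by 50 kb in the empty vector samples. The split and the merged domain on chromosome 3 are neighbours, and the boundary between them sat 50 kb higher in both BAF47 samples. A 2.3 Mb domain on chromosome 6 (136.55 to 138.85 Mb) and a 1.55 Mb domain on chromosome 4 (18.15 to 19.7 Mb) each stood in place of 2 empty vector domains, and a 1.35 Mb domain on chromosome 7 (14.6 to 15.95 Mb) in place of 3.

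Chromosomes differed in the share of their reproducible edges that were gained or lost. As listed, chromosome 9 stood apart with 43.6% (95% Wilson interval 39.9 to 47.4%) against 7.44% on the other chromosomes (Fisher's exact test, adjusted p = 2.02e-131), but with the numbering aligned its share was 5.09% against 7.44% (adjusted p = 0.151). Chromosome 4 was next, with 12.1% (interval 9.96 to 14.5%), and on the aligned numbering the other chromosomes had 7.04% (Fisher's exact test, adjusted p = 2.66e-05, and 0.0247 as listed). Chromosome 13 had 11.3% (8.44 to 14.9%), with an adjusted p of 0.289 as listed and 0.0453 aligned. The lowest shares were 2.72% on chromosome 21 (1.06 to 6.79%), 3.33% on chromosome 19 (1.92 to 5.74%) and 5.05% on chromosome 16 (3.26 to 7.76%). Against the listed average, which chromosome 9 raised, chromosomes 1 (5.66%), 2 (6.75%), 6 (6.30%), 16, 19 and 21 were also below the rest at adjusted p values from 1.48e-05 to 0.00884, which makes 8 chromosomes past the threshold. Aligned, 3 chromosomes passed: 4, 13 and 19 (adjusted p = 0.0214 for chromosome 19 by Fisher's exact test). None passed when edges were joined into boundary bins, where 4 chromosomes had an unadjusted p under 0.05 by Fisher's exact test and chromosome 4 had 8.18% against 5.45%. As listed, 14 passed without BAF47 A. Edges of neighbouring domains are not independent, so these p-values are too small. The balance of gained against lost edges differed on no chromosome (smallest adjusted p = 0.195 aligned by Fisher's exact test, with 2 chromosomes at an unadjusted p under 0.05). Domain numbers of both BAF47 samples exceeded those of both empty vector samples on 4 of the 22 chromosomes (1, 6, 7 and 17) and fell below them on 0, where chance separates 2 samples from 2 on up to 16.7% of chromosomes in each direction. The difference exceeded that between replicates on chromosomes 1 (20.5 against at most 19), 6 (10.5 against 9) and 17 (4.5 against 4).

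**Figure D4:**
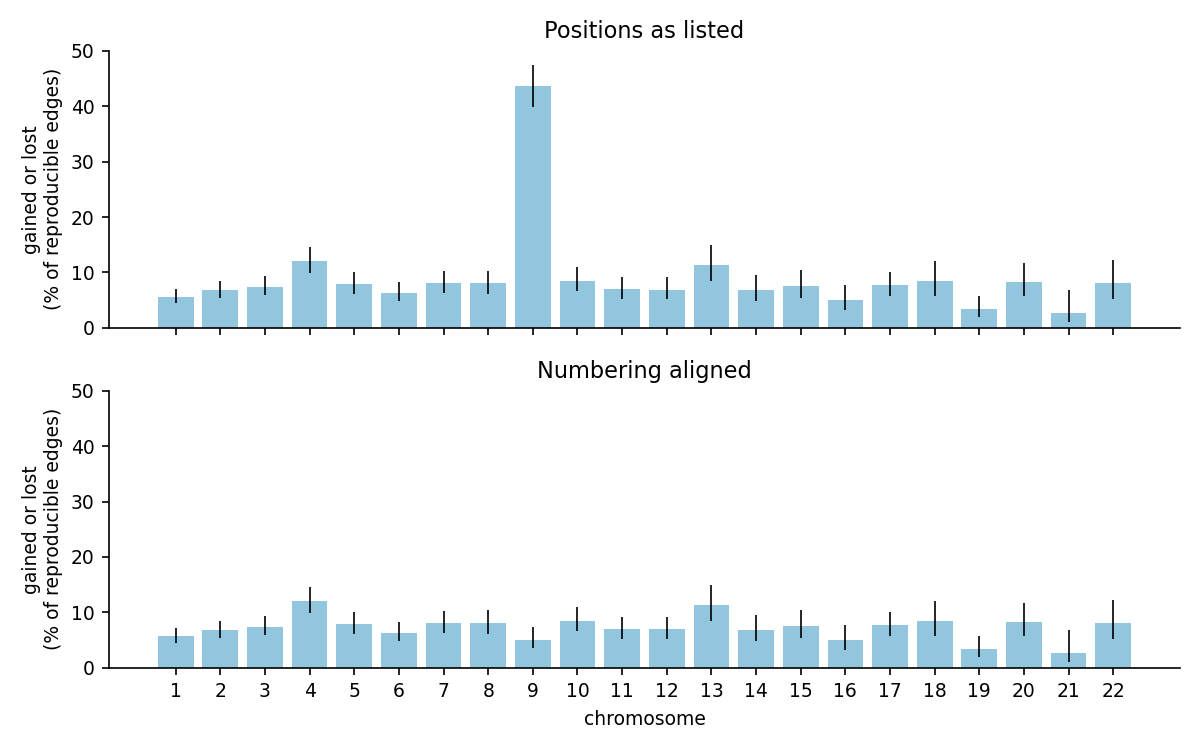
Share of reproducible domain edges (%, y axis) that were gained or lost with BAF47 on each autosome (x axis), as listed (top) and with the numbering aligned (bottom); error bars are 95% Wilson intervals for counting error. Chromosome 9 falls from 43.6% to 5.09% after alignment, and chromosomes 4 and 13 then have the highest shares.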

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

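The aligned numbering, boundary bins, leaving out chromosomes 9 and 20 and the rule of 2 or more inner domains were chosen only after the results were seen. Of 137 alternative values for the main comparisons, 92 stayed and 45 moved. Counts stayed if within 1.5 times the main count, and differences if in the same direction, with 0 differences reversed. No threshold entered this rule, and a count could not change direction under it. Of 480 values for named regions, 445 kept their call and 35 lost it, and no other outcome was scored. Many were fixed in advance. The named edges lay at least 400 kb from the other group, so distances up to 200 kb could not reach it. Leaving out 1 sample could not remove a named edge or domain. Matching distances of 0 and 20 kb and unjoined edges gave the values of the 40 kb rule, as the 50 kb grid requires. Restricting to autosomes changed nothing since only these are listed, and a stricter score could not be tried since the lists hold none. A matching distance of 80 kb gave 182 gained and 179 lost edges and 4 chromosomes past the threshold, and 100 kb gave 104 and 112 edges with 44 split and 38 merged domains (104, 113, 44 and 38 with the numbering aligned). Requiring absence within 100 kb left 99 gained and 105 lost edges and 5 chromosomes, and within 200 kb 37, 65 and 4. Domain starts alone, 1 edge per domain, gave 428 gained and 444 lost edges and 10 chromosomes past the threshold. Boundary bins gave 179 gained, 170 lost and 0 chromosomes, and 178, 171 and 0 aligned. Wider matching leaves fewer edges unmatched by construction, and on the grid the 80 kb setting amounts to matching at 50 kb. Its counts are of single edges and those of boundary bins are of joined edges, so similar counts are not similar shares. On the aligned numbering, 2.59% of reproducible edges outside chromosome 4 differed at 80 kb, against 5.45% of boundary bins. The cause of the step from 4 to 0 chromosomes was not tested. The number of chromosomes past the threshold was 3 with the numbering aligned and 3 without chromosomes 9 and 20. Requiring 2 or more inner domains left 48 split and 32 merged domains. The mean size differed by 0.99 kb where the median differed by 0. With 1 sample left out in turn and the lone sample standing for its group, there were 1143 to 1365 gained and 1055 to 1218 lost edges, 241 to 278 split and 223 to 263 merged domains, and 6 to 14 chromosomes past the threshold (14 without BAF47 A). The agreement within minus between groups stayed from 3.71 to 4.89 points for edges and from 5.67 to 7.45 points for domains, and the domain number difference from 23 to 81. With the replicate letter as a block the differences were the same by construction (52 domains, 23.9 Mb and 104 edges), with the smallest possible sign-flip p of 0.5, and it changed no call; same-letter samples did not deviate together (correlation of 0.0059 over 16353 edges on the aligned numbering). The depth behind each list is unknown, and with 2 samples per group the exact permutation test allows no p below 0.33.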

Other observations

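The tests in this part were chosen after the results were seen, except the count of splits and the test of neighbouring boundaries. Some stretches that the empty vector lists left outside any domain were listed as 1 long domain with BAF47. On chromosome 18, both BAF47 samples listed a domain from 32.1 to 36.25 Mb (4.15 Mb), where the listed domains of the empty vector samples covered 3.61% and 2.41%. On chromosome 11, both listed a domain from 92.65 to 96.75 Mb (4.1 Mb), of which empty vector A listed 1.22% and empty vector B 0%. The same contrast also arose between the BAF47 replicates, in other stretches that both empty vector lists left out. On chromosome 11 from 23.95 to 26.25 Mb, BAF47 A listed 0% and BAF47 B 100%. On chromosome 18 from 58.85 to 61.6 Mb, they listed 1.82% and 100%. Domains over 1 Mb that both samples of a group shared (reciprocal overlap of 80%) without a counterpart in the other group (50%) numbered 4 with BAF47 and 3 with empty vector, against 0 or 1 in each pair of the other splits. The 4 with BAF47 totalled 11.35 Mb, which includes a 1.7 Mb domain on chromosome 5 (47.25 to 48.95 Mb) that was 91.2% listed, as 3 domains, in both empty vector samples. The 3 with empty vector were the 2.05 Mb domain on chromosome 2, the 1.9 Mb domain on chromosome 5 and one of 1.05 Mb on chromosome 8 (2.35 to 3.4 Mb).

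Unlisted stretches of over 1 Mb numbered 28 in each empty vector sample, 18 in BAF47 A and 17 in BAF47 B. Their totals were 51.2 ± 1.91 Mb with empty vector and 31.4 ± 2.47 Mb with BAF47 (SD, n = 2). The exact permutation p was 0.33, the smallest this test can give. Over 500 kb the counts were 71 and 73 against 61 and 54. Over 2 Mb they were 7 and 9 against 7 and 4, so the groups no longer separated. Of 23 such stretches shared by both empty vector samples, 6 overlapped no such stretch in either BAF47 sample. Sequence inside such stretches of both empty vector samples and inside domains of both BAF47 samples came to 7.75 Mb and the reverse to 0 Mb, against at most 0.15 Mb in the other splits. Of the 6 stretches, those on chromosomes 12, 13 and 15 stayed mostly unlisted, with 4.35% to 36.4% inside BAF47 domains. The rest lie on chromosomes 11 and 18, at the long BAF47 domains described above.

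The excess of gained and lost boundaries on chromosome 9 has a technical candidate explanation in the numbering of the lists. If 1 bin was kept in both BAF47 lists and left out of both empty vector lists near the long domain, every later position would sit 1 bin higher. In the BAF47 list with the lower share, 79.0% of the starts beyond the step matched at 1 common offset and 7.18% as listed, which argues against boundaries that moved one by one. With the offset taken only from the domains nearer the step, it was 50 kb in both BAF47 lists, and 84.2% and 75.3% of the starts in the rest of the chromosome matched at it (7.37% and 8.25% as listed), against 81.4% in empty vector B without an offset. The lower share of gained and lost edges after alignment follows largely from the alignment itself, and whether and why a bin was left out stays open, since bins and reads behind the lists were not analysed here.

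The split by vector gave more gained plus lost boundaries than the other splits. The steps in the numbering do not account for all of it, since 949 edges remained after alignment against at most 494 in the other splits. Small shifts of edges do not either, since 217 remained at a matching distance of 100 kb against at most 61. BAF47, an infection or library batch that follows the vector and unequal depth stay open and cannot be told apart, since each vector has its own libraries and no read counts; gained edges made up 51.4% (95% Wilson interval 48.2 to 54.6%) of those that differed, and depth could move edges in both directions. The real split was the 1 of 3 with the largest count, and 3 splits are too few for a share under 0.05.

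Chromosome 4 kept a high share of gained plus lost edges after alignment. Lists that vary more on chromosome 4 between any samples stay open: in the other 2 splits together its share was 1.08 times that of the other chromosomes on identical positions, 1.44 times at 80 kb, 1.41 times at 100 kb and 1.25 times with boundary bins. The split by vector gave 1.71, 2.16, 2.65 and 1.5 times at these settings, but the other splits rest on only 60, 20, 9 and 24 edges or bins. A few clusters of edges could account for it: joined into regions of edges under 500 kb apart, chromosome 4 held 32 of 409 regions where 24.7 would follow from its edges (exact binomial p = 0.144). Its share of regions was 7.82% (95% Wilson interval 5.6 to 10.8%), which holds both the 6.03% of no excess and the 9.91% of the edge count, so this stays open too.

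The hypothesis that neighbouring boundaries change together was tested on boundary bins with the numbering aligned. Among 349 gained or lost bins, 128 pairs stood next to each other in the order of reproducible boundaries, against a mean of 20.1 and a 95th percentile of 27 in 10000 shuffles within chromosomes (permutation p = 0.0001, the smallest these shuffles can give). The other splits had 50 pairs where 4.73 were expected and 68 where 5.67 were, so the excess was not specific to BAF47. Gained and lost bins were counted together, so 1 boundary displaced by more than 1 bin can itself form an adjacent pair. The count therefore cannot tell whether neighbouring boundaries changed together.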
